A study of Homo sapiens with 3 samples.

How the data were processed

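Single-cell RNA was measured in Kelly cells, an established human neuroblastoma line with amplified MYCN and an activating ALK mutation, in 3 states of response to TAE684, an ALK kinase inhibitor. The sensitive library came from cells kept in the vehicle DMSO, the intermediate resistant library from cells grown in 500 nM TAE684 and the fully resistant library from cells grown in 1 µM TAE684. Each state had 1 library, so n = 1 per group. The deposited tables hold UMI counts (counts of distinct RNA molecules) per gene and barcode, with no normalization and no barcode filter, for 32738 gene rows and 737280 barcodes. Per the submitters' processing notes, reads were handled with bcl2fastq and Cell Ranger on the hg19 genome build, and no versions were given. The labels name the 10x Genomics 3' v2 chemistry. No deposited per-sample column was left unused (0 columns). Groups were taken from the response given in the labels.

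The cell rule, the 3 comparisons, the rule for named genes, the gene lists and the settings to vary were fixed before the data were examined. A barcode was called a cell when its UMI total reached 1/10 of the 99th percentile among the library's 3000 barcodes with most UMIs, when at least 500 genes were detected and when at most 20% of its UMIs came from mitochondrially encoded genes. This gave limits of 4767 UMIs in the sensitive, 3750 in the intermediate resistant and 3959 in the fully resistant library. The mitochondrial limit removed 1, 14 and 4 barcodes in that order, and the gene minimum removed 0, 2 and 0. Doublets were kept in the sums. Scrublet, at an expected doublet rate of 0.05, called 0.184% of sensitive, 5.40% of intermediate resistant and 0.250% of fully resistant cells, so its automatic limits found almost no doublets in 2 of the 3 libraries and it served as an alternative only.

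UMIs were summed over called cells and divided by the library's total over all genes (given as CPM). Levels carry exact Poisson 95% intervals, ratios of 2 libraries carry exact conditional Poisson 95% intervals, and shares of cells carry exact Clopper-Pearson binomial 95% intervals. All of these cover counting error only and say nothing about variation between cultures. With 1 library per group no test was run and no p-value was computed. A gene counted as higher or lower by size alone, at a CPM of at least 20 in the higher library and a ratio of at least 2. A gene with 0 UMIs in the lower library was set to a floor of 3 UMIs there, and its ratio was read as a lower bound.

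Named genes followed a rule. In each comparison they were the 12 genes with the highest and the 12 with the lowest ratio among genes with a CPM of at least 50 in the higher library, without mitochondrially encoded genes, ribosomal protein genes and clone-named or unnamed transcripts. From each gene list described, up to 4 measured members with the greatest absolute log2 ratio and a CPM of at least 20 were added. ALK, MYCN, CTCFL, CTCF, AXL, SOX2, VIM, ABCB1, EGFR and IGF1R were always included. Some genes and 1 marker list that these rules cover are not reported here. Any other gene is given as chosen after its values were seen.

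There were 35 gene lists, written from general knowledge of signalling, cell state, metabolism, stress, cell cycle, apoptosis and chromatin genes, and 9 lists of cell type markers. A member was measured at a CPM of at least 5 in 1 of the 2 libraries and was counted as higher or lower at a ratio of at least 1.5. The median log2 ratio of the measured members was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. The resulting percentile describes these libraries and is not a p-value. Lists share members, and the mesenchymal, adrenergic and marker lists overlap.

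For the position of the intermediate resistant library, the log2 step from sensitive to intermediate resistant was divided by the step from sensitive to fully resistant, over genes at least 2-fold different between the last pair. The overlap of both comparisons against the sensitive library was set beside the product of the list sizes over the number of genes and beside 100 draws of unchanged libraries from Poisson distributions around the sensitive sums.

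For values per cell, each cell was thinned at random to 9500 UMIs, and cells with fewer were left out (538 sensitive, 573 intermediate resistant and 561 fully resistant cells). A score per cell was the percentage of UMIs in 100 genes higher in the fully resistant library, out of all UMIs in those and in 100 genes lower there. Its genes, each with a CPM of at least 50 in the higher library and none of them mitochondrially encoded or ribosomal, were chosen on a random split of the sensitive and fully resistant cells, and scores were read in the held-out cells and in all intermediate resistant cells. The score ranges of the end libraries are the central 95% of the held-out cells. Cell cycle phases were called from scores on the S phase and the G2 and M phase lists. Leiden clustering of each library alone (2000 variable genes, 30 components, 15 neighbours, resolution 0.5) served to look for cells of another type and at shifted chromosome runs within a library. Free RNA was read from barcodes with 1 to 50 UMIs.

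For a scan along the chromosomes, genes were matched by identifier to a GRCh38 table used for gene order and chromosome only, and 5127 of 5329 genes of the comparison of the fully resistant with the sensitive library were placed. Windows of 30 neighbouring genes were compared with 100 shuffled gene orders. GC content came from GENCODE transcripts, and 99.5% of the genes in shifted runs had a value.

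Alternatives were TMM and median-of-ratios scaling, scaling without mitochondrially encoded and ribosomal protein genes, 6000 expected cells, a UMI limit of 1/5 of the 99th percentile, all barcodes, a mitochondrial limit of 10%, cells without Scrublet calls, cells without the 5% with most UMIs, the mean over cells of CPM per cell, subtraction of a free RNA profile at 5% of UMIs, equal library totals, and minimum CPM of 5 and 100. For scores per cell they were 50 and 300 genes per direction, no thinning, no cell cycle genes and another random split. A score that counts each gene once per cell was added after seeing the data.

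The ratio step was tested on simulated libraries with 50 genes set 4-fold higher and 50 set 4-fold lower. In the simulation of the fully resistant against the sensitive library it recovered 50 and 49 of them, called 0 of 100 genes set at 1.5-fold and 0 unchanged genes, and its intervals covered 94.9% of the true ratios. The window scan found 10 of 10 planted runs of 60 genes and 0 others. The planted shift was larger than the median log2 size of the reported runs, and fewer shuffled orders were used. That size was 0.57 for fully resistant over sensitive, 0.44 for intermediate resistant over sensitive and 0.42 for fully resistant over intermediate resistant. Recovery of runs of these sizes was not tested. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0. Reads were not aligned again, so sequence variants and splicing were not analysed here, and no DNA copy number was measured.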

Results

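The data were droplet single-cell RNA counts from Kelly neuroblastoma cells in 3 states of response to the ALK inhibitor TAE684, with 1 library per state. The sensitive library held 5445 called cells, the intermediate resistant library 6409 and the fully resistant library 6404. Their cells carried 95266271, 102980142 and 106492064 UMIs in that order, which were 94.9%, 94.9% and 94.3% of each library's UMIs. The median cell had 15971 UMIs and 3620 genes in the sensitive, 15556 UMIs and 3401 genes in the intermediate resistant, and 15956.5 UMIs and 3625 genes in the fully resistant library. Ribosomal protein genes took 36.6%, 39.5% and 33.5% of the UMIs in cells, and mitochondrially encoded genes took 5.57%, 5.14% and 6.57%. Because each group was a single library, no difference given here has a replicate check, and the intervals cover counting error only. Each state also had its own drug condition. Resistance, the TAE684 dose the cells grew in and differences between cultures therefore cannot be told apart for any gene or list below.

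The first comparison asked how cells that grow in the highest dose differ from cells kept in the vehicle. Fully resistant cells carried more transcripts of proneural and neural progenitor transcription factors and of CTCFL, the testis paralog of the chromatin insulator protein CTCF. They carried far less RNA of the G protein regulator RGS5, the noradrenaline transporter SLC6A2 and the vesicular monoamine transporter SLC18A2. RNA of ALK, the drug's target, and of the amplified oncogene MYCN was also lower. Of 5343 genes tested, 291 were at least 2-fold higher and 296 at least 2-fold lower in the fully resistant library, and 47 and 34 of these differed at least 10-fold. Scaling without mitochondrially encoded and ribosomal protein genes gave 384 and 499, and TMM scaling gave 234 and 353.

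CTCFL (ENSG00000124092) had a CPM of 129 (95% interval 127 to 131) in the fully resistant library against 0.577 (0.435 to 0.751) in the sensitive one, a ratio of 223 (171 to 296) in which the lower level is one that free RNA alone could carry (up to 1.28). ALK (ENSG00000171094) had a CPM of 1.25 against 5.44, a level 4.35-fold lower (3.59 to 5.31). MYCN (ENSG00000134323) had a CPM of 446 against 1242, a level 2.79-fold lower (2.76 to 2.81). MYCNOS, which overlaps MYCN on the opposite strand, was 2.13-fold lower, and whether all of its UMIs came from that strand was not tested. CTCF itself was 1.48-fold lower, at a CPM of 45.4 against 67.2. AXL, a receptor kinase linked to inhibitor resistance in other tumours, was at the counting floor, with 1 UMI in the fully resistant library and 0 in the others. The efflux transporter ABCB1 had a CPM of 0.376 against 1.72. EGFR and IGF1R differed little, by 1.16-fold and 1.09-fold.

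Besides CTCFL, the 12 genes with the highest ratios included the proneural factors NEUROD4 and NEUROD1, at a CPM of 85.1 and 111. NEUROD4 had only 1 UMI in the sensitive library, so its ratio of 8106 had a counting interval of 1454 to 320198, while NEUROD1 was 24.6-fold higher. The transcription factor CEBPD had a CPM of 52.6 against 1.21. ARHGAP36 and PKIB, which both encode antagonists of protein kinase A, had a CPM of 338 and 359 and were 184-fold and 176-fold higher. The protease gene PRSS56, at a CPM of 61.8, and IGFN1, at 100.4, were near absence in the sensitive library, at 0.0420 and 0.0945. The calcium binding protein gene S100A1 was 52.5-fold higher, and GCHFR, which encodes the feedback regulator of GTP cyclohydrolase, was 18.5-fold higher.

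Among the 12 genes with the lowest ratios, RGS5 had by far the most RNA, with a CPM of 148 in the fully resistant against 3031 in the sensitive library, 20.5-fold lower (20.1 to 20.8). CAMK2N1, an inhibitor of calmodulin-dependent kinase, was 58.2-fold lower, the collectin gene COLEC11 38.1-fold and the sialidase gene NEU4 24.5-fold. The receptor adaptor DOK4 had a CPM of 14.5 against 370, the neuronal endosome gene NSG2 15.7 against 331 and the chromaffin granule gene CYB561 9.40 against 167. SLC6A2 was 13.6-fold lower, the potassium channel gene KCNH2 9.97-fold and EPAS1, which encodes a hypoxia-inducible factor, 10.7-fold. The intermediate filament gene VIM had a CPM of 4.20 against 62.8. CTAG2 was 18.2-fold lower, but it shares reads with near copies, so its level is uncertain. Several of these genes lay in chromosome runs of neighbours shifted to the same side: NEUROD4 on chromosome 12 (median log2 ratio of the run 0.57), CTCFL on 20 (0.54), DOK4 and SLC6A2 on 16 (-0.93) and VIM on 10 (-0.77), all far smaller shifts than those of the genes named.

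**Figure D1:**
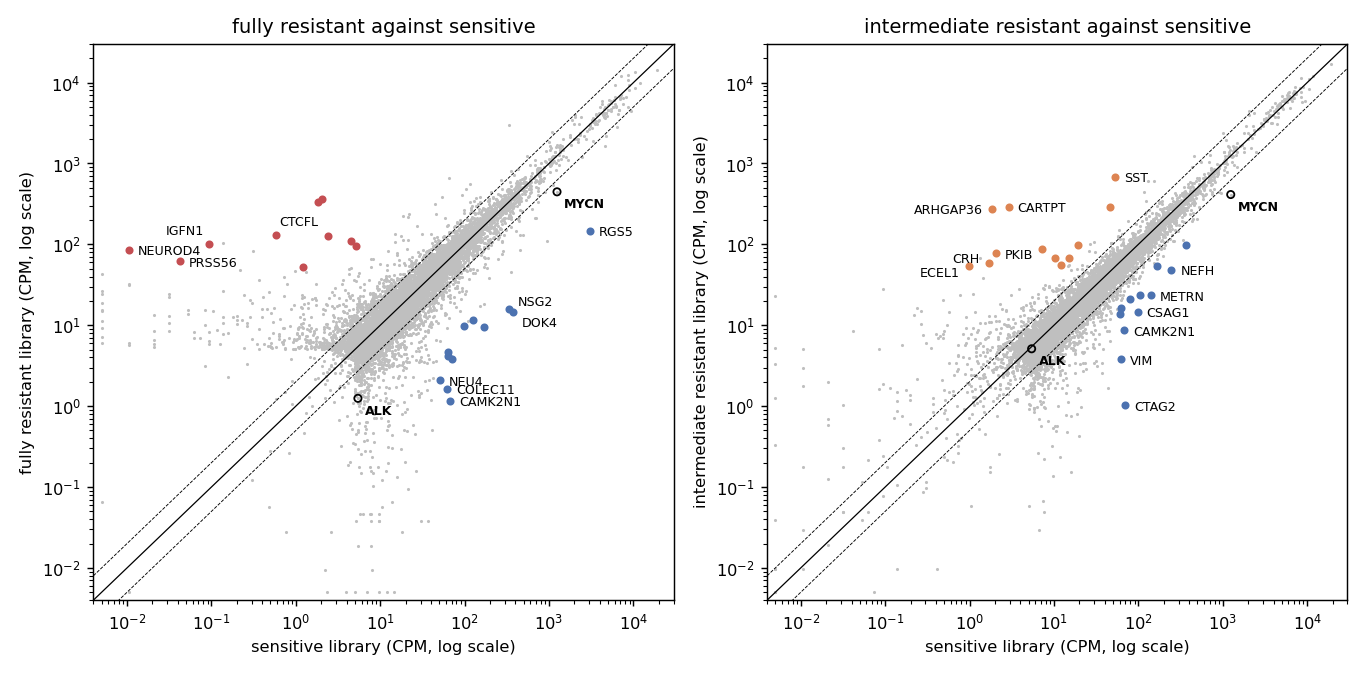
Level of each gene with a CPM of at least 5 in 1 or more libraries, as CPM on log axes, for each resistant library (vertical axes) against the sensitive one, with 1 point per gene, genes of no UMIs in 1 library drawn at the edge, a solid line at equal levels, dashed lines at 2-fold and named genes in colour. CTCFL lies far above the line of equal levels in the fully resistant panel, at a CPM of 129 against 0.577.

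Among the gene lists, the proneural and neural progenitor factors stood out in the fully resistant over sensitive comparison. Of 16 measured, 12 were higher and 1 lower, and the median log2 ratio of 1.53 lay above all random lists (percentile 100). HES6, a target and partner of proneural factors, had a CPM of 312 against 44.5, SOX9 35.2 against 5.17 and SOX2 21.6 against 3.28. The core adrenergic transcription factors, which hold neuroblastoma cells in a noradrenergic state, went both ways. Their median of -0.31 lay at percentile 0.12, with GATA2 5.39-fold and HAND1 3.45-fold lower, yet DACH1 was 8.48-fold higher. The list of catecholamine synthesis and neuropeptides was split in the same way (16 measured, 7 higher and 6 lower, median -0.13). TH, the first enzyme of catecholamine synthesis, had a CPM of 237 against 45.6 and GCH1, which serves the making of its cofactor, was 8.83-fold higher, whereas SLC18A2 was 33.7-fold lower, at a CPM of 1.19 against 40.2. Neuronal cytoskeleton and synapse genes had a median of -0.10 (percentile 3.53), in which NEFM was 10.2-fold higher while CNTN1, NEFH and STMN2 were 5.28-fold, 3.71-fold and 3.65-fold lower.

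Lists on growth signalling and the cell cycle differed in direction. The ERK output list had a median of -0.48 (10 measured, 3 higher and 5 lower, percentile 3.62), with ETV5 3.72-fold lower and CCND1 1.65-fold higher. Receptor kinases and ligands had a median of -0.15 (25 measured, 5 higher and 9 lower), and the GDNF receptor RET was 16.9-fold lower while its partner GFRA1 was 2.32-fold higher. The G2 and M phase list had a median of 0.27, with 11 of 54 genes higher, none lower and a percentile of 99.8, and UBE2C and AURKA were 2.20-fold and 1.85-fold higher. S phase genes stayed near the middle (median 0.11, percentile 55.0), as did cyclins and their kinases (0.18, percentile 79.9), in which CDKN1A was 2.58-fold higher. Endoplasmic reticulum chaperones had a median of 0.47 (percentile 99.9) with HSP90B1 2.77-fold higher, heat shock and immediate early genes 0.24 (percentile 91.1) and the integrated stress response -0.11 (percentile 7.47). Cancer-testis genes, CTCFL among them, had a median of 0.45 with 5 of 10 higher (percentile 98.8), although MAGEA6 and CTAG2 share reads with near copies. CTCF, CTCFL and cohesin genes had a median of 0.18 (percentile 75.1), in which 2 of 16 genes, CTCFL and the cohesin loader NIPBL, were higher.

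Ribosome biogenesis (median -0.10, percentile 1.76), ribosomal proteins (-0.08, percentile 0.78) and nuclear oxidative phosphorylation genes (-0.02, percentile 9.50) were close to 0, and glycolysis and hypoxia genes had a median of -0.22 (percentile 0.87), with 4 of 22 higher and 4 lower. Mitochondrially encoded genes had a median of 0.26 (percentile 97.5), with 4 of 13 higher and 3 lower, and cholesterol synthesis genes one of 0.27 (percentile 95.6), with 6 of 22 higher and 1 lower. The MYC family (-0.10, percentile 18.7), the MYCN neighbours at 2p24 (0.20, percentile 77.6), DNA methylation and histone modifiers (0.12, percentile 60.3), p53 targets (-0.01, percentile 21.8) and YAP targets (0.42, percentile 90.2) had medians inside the random range, as did efflux transporters (-0.27, percentile 13.7) and the retinoic acid pathway (-0.20, percentile 10.9). In the last list, the vitamin A receptor STRA6 was 18.0-fold lower and the binding protein CRABP1 4.69-fold higher. HOX genes had a median of -0.36 (percentile 3.28). Scaling without mitochondrially encoded and ribosomal protein genes raises every CPM, so further members can reach the minimum CPM of 5 and also move a median. For 7 lists the sign of the median depended on the scaling setting, so no direction is given: BCL2 family (0.02), FOXO-induced genes (0.14), Notch (0.04), Wnt (0.11), extracellular matrix (0.05), interferon response (-0.20) and mesenchymal-state genes (0.09). Within them, the Wnt inhibitor DKK1 was 7.14-fold higher, MMP2 and COL4A2 were 18.7-fold and 16.6-fold lower, and B2M, the light chain of MHC class I, was 3.40-fold lower.

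**Figure D2:**
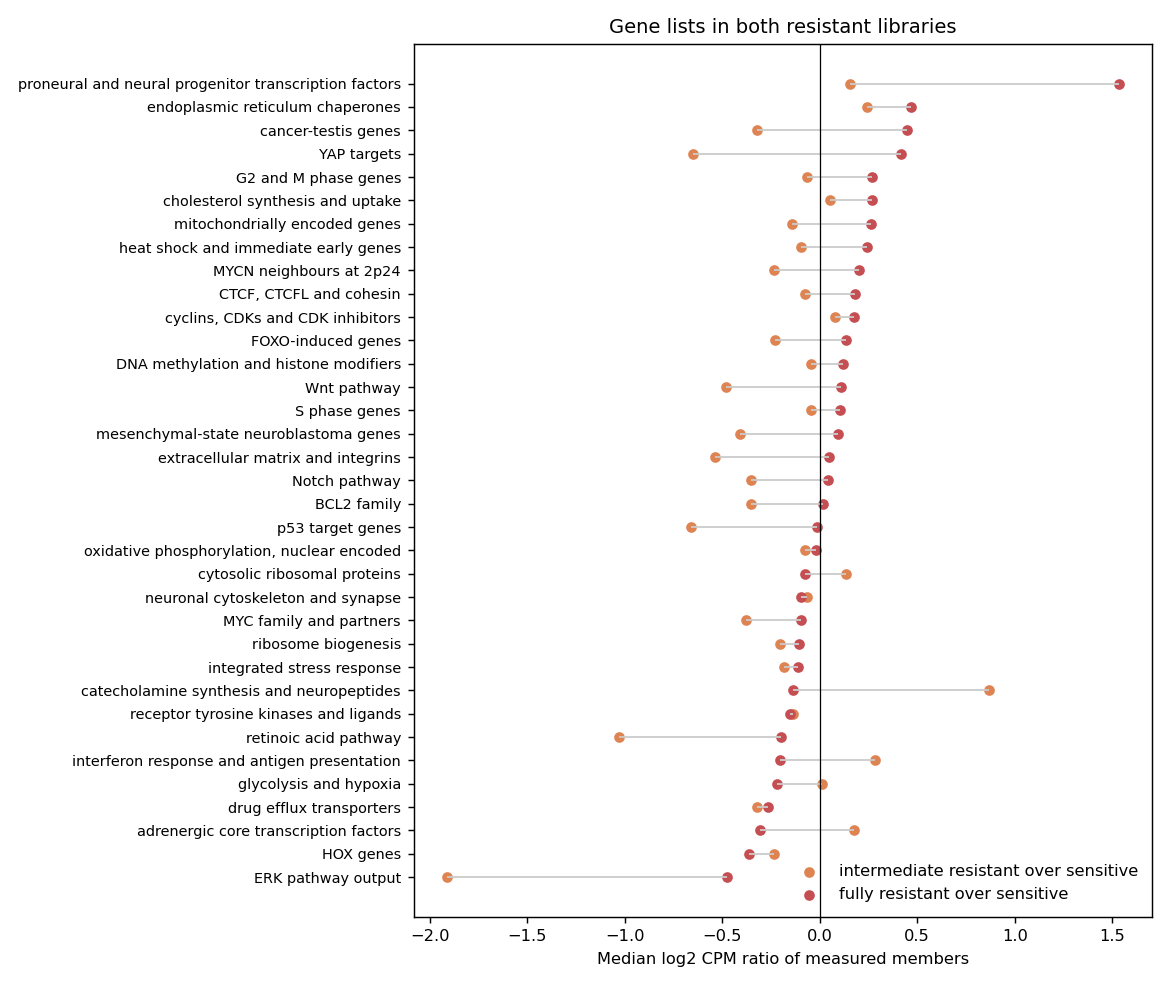
Median log2 CPM ratio of the measured members of each of the 35 gene lists (horizontal axis) against the sensitive library, with 1 point for each resistant library. The proneural list has the highest median in the fully resistant library (1.53) and the ERK output list the lowest in the intermediate resistant library (-1.91), while medians near 0 can change sign with the scaling.

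The second comparison asked what the cells that grow in 500 nM had in common with, or apart from, unexposed cells. Intermediate resistant cells carried more RNA of the neuropeptide genes CARTPT, CRH and SST and of the catecholamine enzymes TH and DBH, and less of 7 of 8 ERK output genes and of 8 of 14 p53 targets. MYCN was near its level in the fully resistant library, while ALK and RGS5 were near that of the sensitive library. Fewer genes differed than in the first comparison, with 88 at least 2-fold higher and 182 at least 2-fold lower of 5045 tested, or 144 and 231 under scaling without mitochondrially encoded and ribosomal protein genes.

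MYCN had a CPM of 413 in the intermediate resistant library, 3.01-fold lower than in the sensitive one (2.98 to 3.04). ALK, at a CPM of 5.12, was 1.06-fold lower, with an interval of 0.939 to 1.20 that includes no difference. CTCFL had a CPM of 3.37, 5.84-fold above the sensitive level by counts (4.38 to 7.91), where free RNA could carry up to 2.11 of this CPM and all of the sensitive level. RGS5 stood at a CPM of 3039 against 3031. EGFR was 2.73-fold higher and SOX2 2.92-fold higher, and IGF1R and ABCB1 were 1.10-fold lower and 1.13-fold higher. CTCF had a CPM of 47.3 against 67.2.

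The neuropeptide genes CARTPT (CPM 290 against 2.91), CRH (58.4 against 1.68) and SST (681 against 53.3) were among the 12 genes with the highest ratios, with PCSK1N, an inhibitor of prohormone processing, 6.51-fold higher and the endopeptidase gene ECEL1 54.6-fold higher. ARHGAP36 was 150-fold higher, close to its level in the fully resistant library, and PKIB was 37.8-fold higher. HRK, a pro-apoptotic BCL2 family member, had a CPM of 87.8 against 7.19. TH was 6.39-fold, the receptor phosphatase gene PTPRG 5.16-fold and the calcium sensor TESC 4.52-fold higher. MAGEA6 was 4.59-fold higher and CTAG2 68.7-fold and CSAG1 6.70-fold lower, all of them genes that share reads with near copies. VIM was 16.5-fold lower, at a CPM of 3.80. CAMK2N1 was 7.81-fold, the neurotrophic factor METRN 6.00-fold, the neurofilament gene NEFH 5.08-fold and CRABP1 4.46-fold lower. HAGHL, LIMCH1, the Wnt antagonist SFRP1, DOK4 and CYB561 were between 3.11-fold and 4.45-fold lower. HRK and TESC lay in a run of genes on chromosome 12 with a median log2 ratio of 0.44, TH on 11 (0.88), VIM on 10 (-0.89), NEFH on 22 (-0.50) and DOK4 on 16 (-0.58).

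Genes downstream of ERK gave the lowest median of the 35 lists in the intermediate resistant over sensitive comparison. Of 8 measured, 7 were lower and CCND1 alone was higher, and the median log2 ratio of -1.91 lay below all random lists (percentile 0). Under scaling without mitochondrially encoded and ribosomal protein genes this median was -1.35. ETV5, an ETS factor induced by ALK signalling, was 6.06-fold lower. The p53 targets had a median of -0.66 (percentile 0.01), with 8 of 14 lower and none higher, among them PHLDA3 (10.3-fold), ZMAT3 (3.10-fold) and BAX (2.39-fold). The catecholamine and neuropeptide list had a median of 0.87 (percentile 100), with 8 of 15 higher and 2 lower, and TH, DBH and CHGB stood at 6.39-fold, 3.99-fold and 2.16-fold the sensitive level. The adrenergic factors (0.17, percentile 99.5) had only a small shift, with KLF7 2.59-fold lower and SIX3 2.49-fold higher. Extracellular matrix genes had a median of -0.54 (percentile 0.13), with 7 of 14 lower and 1 higher, and mesenchymal-state genes one of -0.41 (percentile 0.53), with 6 of 16 lower and 1 higher. ITGB1 and ZEB1 in these lists were 2.52-fold and 2.58-fold lower. Wnt genes had a median of -0.48 (percentile 0.755), with 4 of 9 lower and 2 higher. The retinoic acid pathway had a median of -1.03 (percentile 0.01), but only -0.25 under scaling without mitochondrially encoded and ribosomal protein genes. That scaling raises every CPM and lets further members reach the minimum CPM of 5, so the 2 medians cover different genes. BCL2 family genes had a median of -0.35 (percentile 1.84), with 5 of 13 lower and only HRK higher, and YAP targets one of -0.65 (percentile 1.80), with 3 of 5 lower. Endoplasmic reticulum chaperones had a median of 0.24 (percentile 100), with 2 of 16 higher and 0 lower, and ribosomal proteins one of 0.13 (percentile 100), with 4 of 83 higher and 3 lower. Among receptors, the GDNF family receptor GFRA3 was 26.7-fold and the growth factor gene IGF2 2.74-fold higher, and RET was 5.79-fold lower. Medians of CTCF and cohesin, DNA methylation, S phase and G2 and M phase genes changed sign with the scaling or with the members it admitted.

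**Figure D3:**
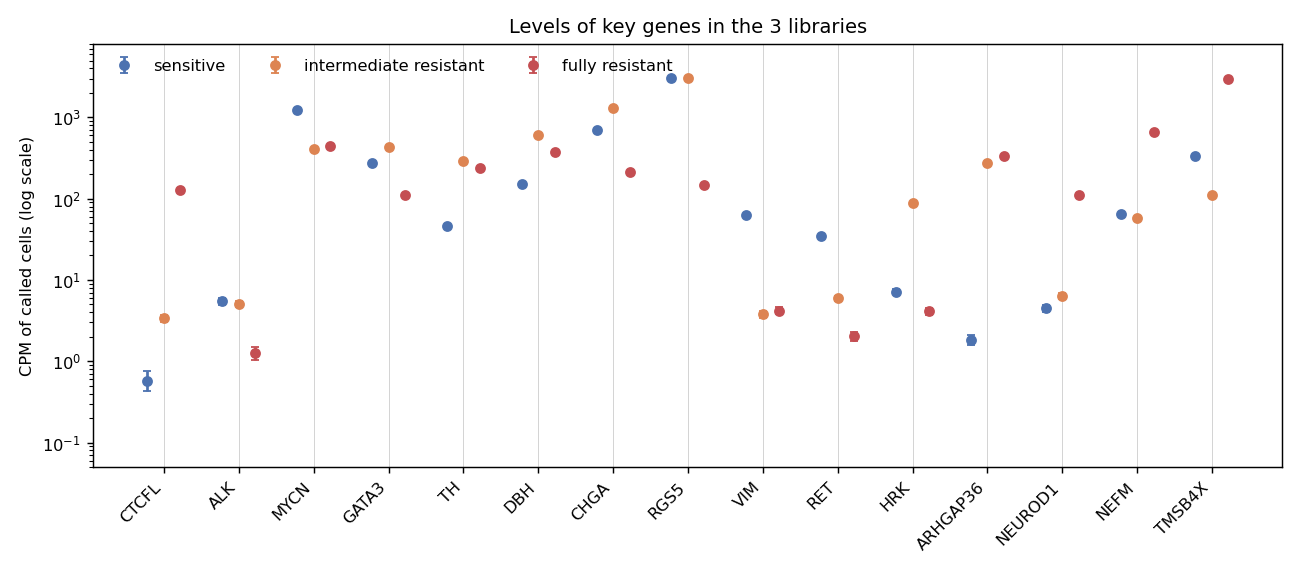
Level of 15 genes as CPM of called cells on a log axis, with 1 point per library and exact Poisson 95% intervals as bars. MYCN is lower in both resistant libraries (413 and 446 against 1242), whereas ALK (1.25 against 5.44) and RGS5 (148 against 3031) are lower in the fully resistant library.

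The third comparison asked what sets full resistance apart from the intermediate state. Fully resistant cells carried more RNA of CTCFL and of the proneural factors NEUROD4 and NEUROD1. They carried less RNA of the neuropeptide genes CRH and CARTPT, of HRK, and of RGS5 and its relative RGS4. Genes of the ERK output and p53 lists were more often higher than lower. The median log2 ratio of all tested genes was 0.17, which TMM scaling moved to 0.03, so list medians are given relative to that of all genes. There were 233 genes at least 2-fold higher and 145 lower of 5166, so that 61.6% of these were higher, against 47.2% under TMM scaling and 49.5% under median-of-ratios scaling. Scaling without mitochondrially encoded and ribosomal protein genes gave 274 higher and 280 lower.

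CTCFL was 38.2-fold higher in the fully resistant than in the intermediate resistant library (34.4 to 42.6). NEUROD4 was 28.6-fold and NEUROD1 17.4-fold higher. ALK was 4.10-fold lower (3.38 to 4.99). MYCN, at 446 against 413, was 1.08-fold higher, and its log2 ratio of 0.11 became -0.03 under TMM scaling, so it had no direction between the resistant libraries. MGST1, a membrane glutathione transferase gene, had a CPM of 235 against 2.75, and the secreted Wnt inhibitor DKK1 126 against 4.41. CRABP1 was 20.9-fold, PPAPDC1A 19.9-fold and the GTPase gene RAB31 16.7-fold higher. TMSB4X was 26.4-fold higher and MAGEA12 15.4-fold higher, and both share reads with near copies.

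PTPRG was 32.2-fold lower, HRK 21.3-fold, RGS5 20.5-fold and RGS4 11.4-fold lower in the fully resistant than in the intermediate resistant library. CRH and CARTPT were 11.5-fold and 10.2-fold lower, the thyroglobulin gene TG 15.2-fold, NSG2 12.4-fold and VSTM2L 10.2-fold. EPAS1, MEIS2 and DOK4 were 9.53-fold, 7.74-fold and 6.88-fold lower. The cell cycle inhibitor CDKN2A had only 5 UMIs in the fully resistant library, a CPM of 0.0470 against 31.3, which was 667-fold lower with a counting interval of 286 to 2056. Counts do not part a lost gene from a silent one, and this was not tested. PTPRG lay in a run on chromosome 3 with a median log2 ratio of -0.88, DOK4 on 16 (-0.34) and CTCFL on 20 (0.50), where VSTM2L went against its run.

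Relative to all genes, the proneural list had a median of 1.01 in the fully resistant over intermediate resistant comparison, with 11 of 16 higher and none lower, and HES6 was 6.41-fold higher. The adrenergic factor list and the catecholamine and neuropeptide list both lay at -0.49, with GATA3 3.92-fold and CHGA 6.02-fold lower. YAP targets (1.07), ERK output (0.78), cancer-testis genes (0.40), mesenchymal-state genes (0.33), p53 targets (0.30) and extracellular matrix genes (0.26) had medians above that of all genes. Within these lists, TEAD2 was 53.6-fold, ETV1 6.36-fold, CDKN1A 76.6-fold and SERPINE2 3.78-fold higher. CDKN1A was far less raised over the sensitive library, so most of its ratio here reflects a low level in the intermediate resistant library. Ribosomal proteins lay at -0.40 and neuronal cytoskeleton genes at -0.36, while G2 and M phase genes lay at 0.13. Interferon genes lay at -0.57, which scaling without mitochondrially encoded and ribosomal protein genes reversed. In this comparison 10 of the 35 list medians changed sign with the scaling and 25 did not.

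Set gene by gene against both ends, the intermediate resistant library lay between the others for most genes. Over the 587 genes at least 2-fold different between fully resistant and sensitive cells, its median position was 0.369 on a scale from 0 (sensitive) to 1 (fully resistant). It lay between the ends for 426 genes (72.6%), beyond the sensitive library for 106 (18.1%) and beyond the fully resistant one for 55 (9.37%). Genes higher in the fully resistant library had a median position of 0.285 and lower genes one of 0.431. Both end libraries entered the choice of genes and the position. Of the 4964 genes tested in both comparisons against the sensitive library, 101 were at least 2-fold lower in both, where independent lists of 296 and 182 genes would share 10.9, and 44 were higher in both, where lists of 158 and 62 would share 1.97. The higher lists held only 158 of 291 and 62 of 88 genes, because a gene low in the sensitive library was tested in both comparisons only if its CPM reached 20 in both resistant libraries, which favours shared genes, so no excess is read for higher genes. Both comparisons also use the same sensitive library, so independent lists are not the value without change, and no excess is read for lower genes either. Unchanged libraries drawn by Poisson gave no gene at 2-fold between the fully resistant and the sensitive library in 100 draws, so they could share none. They carry counting noise alone and no variation between cultures. Across genes, which are not independent replicates, the log2 ratios of both comparisons had a correlation of 0.653 and a covariance of 0.290, against 0.523 and 0.000581 in the draws. The draws correlate by construction, because both ratios share the sensitive library, so the 2 correlations are not compared. Their small covariance argues against shared counting noise as a large part. Variation of the shared sensitive culture is not in the draws and may add to the correlation.

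Cell by cell, the question was whether the intermediate resistant culture mixed sensitive and fully resistant cells. On the score built from genes that part the end libraries, the median was 24.3 in sensitive, 41.2 in intermediate resistant and 81.1 in fully resistant cells, and the central 95% of the end libraries spanned 17.3 to 33.7 and 63.1 to 89.8. Of 5836 intermediate resistant cells, 89.6% (88.8 to 90.4) lay between these ranges, 9.90% (9.15 to 10.7) in the sensitive range and 0.497% (0.333 to 0.713) in the fully resistant range. The share in the sensitive range depended on the genes and the random split, from 5.38% with another split to 26.3% with 50 genes per direction. RGS5 made up 15.4% of the UMIs of the lower genes, and H3F3B 13.6% of those of the higher genes.

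**Figure D4:**
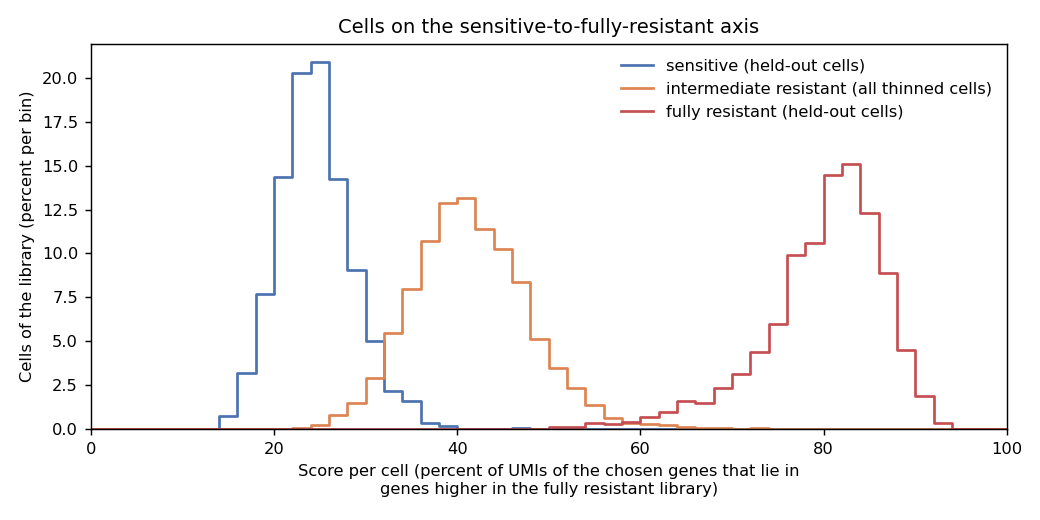
Distribution of the score per cell, the percentage of UMIs of the chosen genes that lie in genes higher in the fully resistant library (horizontal axis), as percent of each library's cells per bin, with 1 line per library. Intermediate resistant cells form 1 peak around a median of 41.2, between medians of 24.3 and 81.1.

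CTCFL was detected in 64.7% (63.5 to 65.9) of fully resistant cells thinned to 9500 UMIs, in 3.12% (2.69 to 3.60) of intermediate resistant and in 0.632% (0.430 to 0.896) of sensitive cells. If every fully resistant cell had held the mean level, 69.9% would have shown a UMI. No cell type without the gene was at hand, so barcodes of 1 to 50 UMIs gave the background. These held a median of 2 UMIs, and 0.0727%, 0.00226% and 0.00108% of them had a CTCFL UMI in the same order of libraries. As CPM, this free RNA held 119, 3.86 and 1.84 of CTCFL, against 129, 3.37 and 0.577 in cells, so the few CTCFL UMIs in sensitive cells are not read as expression. A MYCN UMI was found in 99.7%, 92.2% and 93.8% of sensitive, intermediate resistant and fully resistant cells, against 0.707%, 0.257% and 0.275% of the barcodes of 1 to 50 UMIs. ALK was seen in 5.16%, 5.14% and 1.04% of cells, against 0.00301%, 0.00513% and 0% of those barcodes. These shares differ with depth, and on the CPM scale the free RNA held 1227, 406 and 451 of MYCN and 5.16, 8.03 and 0 of ALK, against 1242, 413 and 446 and against 5.44, 5.12 and 1.25 in cells.

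Marker lists were read in the library sums, which show shifts between libraries and cannot reveal a small group of cells of another type. No cell type was assigned to the clusters. No lymphoid, myeloid or erythroid marker was measured in any comparison (0 in each list). In the fully resistant library, adrenergic markers had a median log2 ratio of -0.22 over the sensitive library (9 measured), and in the intermediate resistant library 0.66. Mesenchymal markers had a median of 0.32 in the fully resistant library, with 2 of 5 higher and 2 lower, and of -3.60 in the intermediate resistant library, with 3 of 3 lower. In the fully resistant library, fibroblast markers gave -0.59 (3 measured), the epithelial marker KRT19 alone -3.70 and the endothelial marker CLDN5 alone 6.63. CLDN5 was a top gene of cluster 4 of that library, at a CPM of 80.2 against 24.7 in the other cells. TH and DBH were top genes of the same cluster, so CLDN5 is not read as a sign of endothelial cells. By phase scores, 48.2% of sensitive and 37.6% of fully resistant cells were called G2 or M, while the CPM of the G2 and M phase list was highest in the fully resistant library, so no order of cycling was read.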

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

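The free RNA tests and the test of fewer copies of the amplified region were chosen only after the results were seen; the others were set beforehand.

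Against the sensitive library, 3 genes were at least 2-fold higher in the intermediate resistant and at least 2-fold lower in the fully resistant library. TG had a CPM of 30.2 in sensitive, 80.7 in intermediate resistant and 5.32 in fully resistant cells. The neuroendocrine factor INSM2 had 124, 252 and 49.7, and the homeobox factor MEIS2 125, 343 and 44.3. In the other direction, 3 genes were lower in the intermediate resistant and higher in the fully resistant library. TMSB4X had 338, 112 and 2970, MGST1 22.0, 2.75 and 235, and CRABP1 104, 23.4 and 488. In barcodes of 1 to 50 UMIs, TMSB4X had a CPM of 512, 330 and 2980, above the cell level in the sensitive and intermediate resistant libraries. These genes stood out because the 2 resistant libraries differed from the sensitive one in opposite directions, and the difference was not tested, since each state had 1 library.

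CTCFL UMIs were seen in the sensitive and intermediate resistant libraries, at 0.577 and 3.37 CPM, far below the fully resistant level of 129. Index hopping from the fully resistant library would place them at barcodes of fully resistant cells, but 0 of 62 UMIs in the sensitive library (0%, up to 5.78%) and 0.813% (0.168 to 2.36) in the intermediate resistant library lay there, near the 1.17% and 0.873% of all UMIs. Carried-over fully resistant cells are argued against in the intermediate resistant library, where 0.962% of cells with a CTCFL UMI lay in the fully resistant score range. Free RNA held 1.14 times the cell level there (0.586 to 2.02), but it could carry at most 2.11 CPM, below the lower bound of 3.02 for the cells, so it may supply part and not the whole. In the sensitive library, where free RNA held 3.19 times the cell level and could carry up to 1.28 CPM, it could supply all of the CTCFL UMIs and stays open, beside a low level of transcription, which is untested.

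MYCN RNA was lower in both resistant libraries. Scaling by the methods tried is argued against. The ratio of fully resistant over sensitive was 0.359 in the main setting, 0.336 under TMM and 0.342 under median-of-ratios scaling. It was 0.346 under scaling without mitochondrially encoded and ribosomal protein genes. The highest ratio over 15 settings was 0.361, but most of these are not scalings, and a minimum CPM cannot change a gene's ratio. Loss of MYCN from most cells is argued against too in the fully resistant library, since 93.8% of its thinned cells had a MYCN UMI. A smaller subset without MYCN is not excluded. Free RNA there held a MYCN CPM of 451 against 446 in cells, so a UMI need not come from the cell it was found in. The intermediate resistant library was not part of this test. Fewer copies of the amplified region could lower it, and the neighbours DDX1 and NBAS had ratios of 1.18 (1.15 to 1.20) and 1.07 (1.00 to 1.13), but whether they are amplified together with MYCN in these cells is not known from counts. Copy number and a biological effect of drug exposure on MYCN transcription therefore cannot be told apart here.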

How the results depend on the processing

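A score that counts each gene once per cell was the only alternative chosen after the results were seen. Of 1470 values of 105 list medians under the alternatives, 1 reversed a median far from the random lists: the interferon median of fully resistant over intermediate resistant, at 0.10 (0.0999) under scaling without mitochondrially encoded and ribosomal protein genes. The greatest move was that of the retinoic acid median of fully resistant over intermediate resistant, from 0.08 to -0.84 under the same scaling. That scaling raises every CPM, and both changes came mostly from members that newly reached the minimum CPM of 5. List medians changed sign with the scaling in 7 lists of fully resistant over sensitive, 4 of intermediate resistant over sensitive and 10 of fully resistant over intermediate resistant, the interferon list included. Of 2520 values of named gene ratios, 240 moved and 0 reversed a ratio of at least 2-fold. The minimum CPM of 5 and of 100 cannot change a gene ratio or a list median, so their values among the 2520 and the 1470 were fixed in advance. Phase shares moved in 16 of 27 values and shares of cells with a UMI in 8 of 27. The MYCN ratio over the sensitive library ranged from 0.336 to 0.361 in fully resistant and from 0.330 to 0.347 in intermediate resistant cells. Scaling without those genes raised the lower genes of fully resistant over sensitive to 499, the higher genes of intermediate resistant over sensitive to 144 and the lower genes of fully resistant over intermediate resistant to 280, and it raises every remaining CPM and also shifts the ratios. A minimum CPM of 5, which admits more genes, gave 659 higher and 717 lower for fully resistant over sensitive, 227 and 457 for intermediate resistant over sensitive, and 547 and 378 for fully resistant over intermediate resistant. A minimum of 100, which admits fewer, gave 70 and 63, 23 and 31, and 46 and 33. The other alternatives left these counts within 1.5-fold. The median position of the intermediate resistant library stayed between 0.368 and 0.390 and the share of genes between the ends from 72.2% to 75.4%. The intermediate cells in the sensitive range and between the ranges were 26.3% and 72.9% with 50 genes per direction, 7.21% and 91.1% with 300, 7.58% and 92.0% without thinning, 7.15% and 92.4% without cell cycle genes, 9.05% and 90.4% with the stricter UMI limit, 5.38% and 94.1% with another random split, and 17.5% and 82.2% with each gene counted once. The stricter UMI limit scored the same 5836 intermediate resistant cells as the main setting, so its change came through the end libraries alone. The cause of the other changes was not tested. No paired analysis was possible because each state had 1 library. Depth limits genes near the floor, such as NEUROD4, PRSS56 and IGFN1 in sensitive cells.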

Other observations

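The test of a mix of cells was chosen only after the result was seen; the tests of gene order, of GC content and level, and of copy number were set beforehand.

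Within the fully resistant library several abundant genes, chosen after their values were seen, were missing from more cells than an even level would leave. RGS5 was detected in 38.4% of thinned cells where an even level would give 77.1%, NEUROD1 in 37.8% against 64.9%, NEFM in 71.0% against 99.8%, TH in 53.4% against 89.0% and DBH in 75.4% against 97.2%. The gap was smaller for CTCFL, at 64.7% against 69.9%. These genes differed between clusters of that library. Cluster 6 (12.8% of cells) had a NEFM CPM of 2622 against 378 in the other cells, and NEUROD1 403 against 68.4. RGS5 had 389 against 130 in cluster 5 (8.40% of cells). In cluster 4 (22.2% of cells), TH had 494 against 170 and DBH 734 against 286. The genes may have helped to form the clusters, so this describes them only. In the sensitive library VIM was detected in 30.8% of cells against 46.5%, and in the intermediate resistant library HRK in 44.5% against 56.5% and TH in 78.7% against 94.1%. Barcodes of 1 to 50 UMIs, with a median of 2 UMIs against 9500 in thinned cells, gave the background. In the fully resistant library 0.0907% of them had a UMI of RGS5, 0.0826% of NEUROD1, 0.477% of NEFM, 0.153% of TH and 0.179% of DBH, and the free RNA there held an RGS5 CPM of 149 against 148 in cells. VIM was seen in 0.0338% of such barcodes in the sensitive library, and HRK and TH in 0.0297% and 0.216% in the intermediate resistant library.

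CDKN2A had a CPM of 7.87, 31.3 and 0.0470 in the sensitive, intermediate resistant and fully resistant libraries. Its neighbour MTAP had 10.6, 9.70 and 0.0563, the last from 6 UMIs, which was 172-fold below the intermediate resistant level (78.8 to 470). KLHL9, further along the chromosome, had 16.1, 11.7 and 7.47, and CAAP1 19.0, 16.5 and 9.94. MTAP, KLHL9 and CAAP1 were chosen after their values were seen. Whether these genes are lost from the DNA was not tested, since no DNA was measured.

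Of 13712 CTCFL UMIs in the fully resistant library, the cell with most held 14, and 2173 cells held 3 or more. The sensitive and intermediate resistant libraries had 0 and 1 such cells among 55 and 347 UMIs.

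Along the chromosomes, neighbouring genes differed together between the fully resistant and the sensitive library in 15 runs, 7 higher and 8 lower, that held 1225 of 5127 placed genes. Those with most genes were on chromosomes 12 (216 genes, median log2 ratio 0.57), 22 (145 genes, -0.57), 20 (132 genes, 0.54) and 16 (118 genes, -0.93), and 38.0% of the higher and 48.4% of the lower 2-fold genes lay in runs of their own side, against 11.4% and 12.4% of all placed genes. The runs were found from the same ratios, so this difference was partly built in and is not read as a result. The intermediate resistant library had 11 runs against the sensitive one. Within that library, clusters 2, 3 and 9, chosen after their values were seen, differed from its other cells: of the genes outside the set used for clustering, 1.96%, 0% and 7.84% of those in the run on chromosome 13 were higher, and 91.7%, 89.3% and 82.1% of those in the run on chromosome 16. In the run on chromosome 12 the shares were 5.38%, 11.3% and 18.8%. The run on chromosome 20 split the cells otherwise, with 91.1%, 77.8% and 84.4% in these clusters, 88.9% in cluster 1 and 4.44% in cluster 4.

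A chance order of genes is argued against, since 0 of 100 shuffled orders gave a window as far from 0, and expression level and GC content are argued against as the whole cause, since 93.8% of the median size of the runs was kept after both were taken off. A difference in copy number between the cultures may explain the runs, but 78.6% (75.7 to 81.2) of genes of low CPM in them, which were not used to find them, lay on the run's side, short of the 80% set beforehand. The same share was 80.6% (77.5 to 83.4) for intermediate resistant over sensitive and 80.1% (76.7 to 83.2) for fully resistant over intermediate resistant, with intervals that span 80%, so copy number stays open beside regional regulation. In the intermediate resistant library the UMI shares of the lower runs on chromosomes 13 and 16 had a correlation of -0.55 across cells, and 1 of 100 random pairs of gene sets was as far below 0 (at -0.65), while the sensitive and fully resistant libraries gave -0.02 and -0.03, with 7 and 12 of 100 random pairs as low. This is consistent with a mix of cells that carry different runs in the intermediate resistant culture, a hypothesis found and tested on the same cells.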
